A study of Rattus norvegicus with 6 samples.

How the data were processed

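Total RNA of the renal cortex of 6 male Sprague-Dawley rats was measured on 6 one-colour (Cy3) Agilent oligonucleotide arrays. Per the labels, 3 rats received corn oil, the vehicle, and 3 rats received o-nitroanisole, a nitroaromatic compound also called 2-methoxynitrobenzene, at 400 mg/kg/day, both for 4 weeks. The rats were 5 weeks old at purchase. The labels call the 3 arrays of each group biological replicates.

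Per the file headers, the scanner files hold spot intensities from Agilent Feature Extraction, version 10.7 per the submitters' processing notes. Per the file headers, the processed signal is a background-subtracted intensity with spatial and multiplicative detrending within the array and no scaling between arrays. The deposited value table holds a ratio on a linear scale without centring. Each column equals the processed signal of 1 scanner file divided by that array's 75th percentile, as checked over probes well above background on that array. In the deposited table, the columns of the o-nitroanisole samples matched their own scanner files for 100% of these probes within 1%. The corn oil columns matched the corn oil scanner files in another order: column 1 held the file of replicate 3, column 2 that of replicate 1 and column 3 that of replicate 2. The group of each array is the same in both sources, and the number of each corn oil rat is not settled. Scanner files were used for the main analysis and the value table for an alternative.

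Of 61657 non-control probes, 84 RNA spike-in probes were left out of the tests. Probes were named through their RefSeq accession, without version, in a gene table of assembly GRCr8: 27460 of 33356 accession-bearing probes matched, giving 15284 gene symbols, and 34113 probes stayed unnamed here, 796 of them custom probes. The array headers name build rn4, and no coordinates are given for this reason. Log2 processed signal minus the array's 75th percentile over non-control probes was the expression value. Spots marked as outliers were set to missing, no non-control probe had more than 1 spot, and no probe was saturated. A probe entered the tests if it was well above background on every array of at least 1 group, which 41096 probes were. A gene was represented by its brightest probe, and unnamed probes were kept as features of their own. This gave 32428 features, called genes in the counts, of which 11815 had a symbol and 6111 of those had several tested probes.

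The 75th percentile of the processed signal lay between 905 and 1041 units over the arrays, and 66.4% to 71.5% of non-control probes were well above background. The number of arrays, 3 per group, limits the precision. All corn oil arrays lay on slide 1 and scan 1 and all o-nitroanisole arrays on slide 2 and scan 2, so slide and scan cannot be told apart from the group.

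Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with defaults), with Benjamini-Hochberg adjustment at 0.05. All log2 differences are o-nitroanisole minus corn oil, with the moderated standard error (SE). Lists of response genes and of cell type markers, 27 in all, were tested with camera at a preset inter-gene correlation of 0.01. The table files were read and the plots drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The design, the lists, 17 alternatives and the rule for named genes were fixed before the data were examined, and 5 alternatives were added after seeing the data. The default eBayes fit stayed the main test after its result was known, although other planned settings called more genes.

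The rule for named genes took the 5 highest and 5 lowest symbol-bearing genes past the threshold, and up to 2 per direction detected in 1 group only. It also took members of each list past the threshold, and otherwise the list member with the largest difference. Havcr1, Cyp1a1, Nqo1, Hmox1 and Cdkn1a were to be named in any case; a probe for Mki67 was not matched by accession. For the sterol synthesis list and the endothelium and vessel wall list, the member that the rule names is not reported here. Because no gene passed, the first parts of the rule named none. The same parts were then applied to the fit with trend and robust options, and those genes, and the further list members given as examples, were chosen after their values were seen. Where a gene was not well above background on any array of 1 group, its fold is a bound: the mean of the brighter group against the mean, over the dim group's arrays, of the higher of the lowest signal among probes well above background and the probe's own.

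The planned normexp alternative was to use the mean signal column. That column is not used here because the files as read give a median signal, so normexp with an offset of 50 was run on the median signal and the median local background. The planned slide block could not be fitted, since no slide held both groups.

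The tests were tried on simulated data for 32412 genes without missing values, with 200 genes changed in each of 5 runs. With each gene's variance drawn from its posterior, the default fit called 18.2% of genes changed 1.5-fold, 61.5% of those changed 2-fold and 87.6% of those changed 4-fold, with 29 false calls in all. The fit with trend and robust options called 21.5%, 59.7% and 87.3%, with 26 false calls. The variances were first set to the moderated values; the draw replaced them after the real result was known, because they vary less between genes than the data do. With the moderated values the default fit called 23.3%, 66.9% and 92.1%. The changed genes were drawn at random, and with drawn variances both fits called like shares, whereas the real data gave 0 and 522 genes. The simulation therefore does not show how many real changes of a given size were missed. A list shifted by 0.5 log2 was called in 20 of 20 runs by camera with the preset correlation and by fry, and in 18 of 20 by camera with an estimated correlation, with independent genes. Of 520 tests of the other lists, camera with the preset correlation called 1, fry 4 and camera with an estimated correlation 0. Some of those lists share genes with the shifted list, the NRF2 targets, so they were not all without a shift. The genes of those lists were independent too. In the real data, other splits of the 6 arrays into 3 and 3 called up to 10 of the 27 lists by camera with the preset correlation. The simulated error rates therefore cannot be carried over to the real lists.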

Results

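Gene expression in renal cortex was compared between 3 rats given corn oil and 3 rats given o-nitroanisole for 4 weeks, which asks how 400 mg/kg/day of this nitroaromatic compound alters kidney transcripts. Each rat gave 1 array. Between 66.4% and 71.5% of non-control probes were well above background per array. Pearson correlations between arrays over genes lay between 0.990 and 0.992 within corn oil, 0.991 and 0.992 within o-nitroanisole, and 0.986 and 0.992 between the groups. The first principal component held 34.7% of the variance and placed all o-nitroanisole arrays on one side of all corn oil arrays.

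Cyp1a1, a cytochrome P450 under the aryl hydrocarbon receptor, was not well above background on any corn oil array and was well above it on all 3 o-nitroanisole arrays, a level at least 7.30-fold higher (adjusted p = 0.0820). That bound holds for the processed signal. Under normexp background correction the fitted log2 difference was 1.43 (adjusted p = 0.0602), which is smaller than the bound. The offset of 50 added under normexp draws the folds of dim probes toward no change by construction, so this value and the bound are not like for like. Hmox1, which breaks down heme, was 1.15 ± 0.22 log2 higher (SE, n = 3 per group, adjusted p = 0.116), and Nqo1, a quinone reductase, 0.93 ± 0.25 higher (adjusted p = 0.155). Tff3, a secreted trefoil peptide, was lower by a log2 difference of -2.02 ± 0.40 (adjusted p = 0.117). None of these passed the threshold of 0.05 with limma's default moderation.

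With limma's default moderation, 0 of 32428 genes passed an adjusted p of 0.05, and the smallest adjusted p was 0.0711. At an unadjusted p under 0.05 there were 6142 genes, 3832 higher and 2310 lower, where chance alone would give 1621. Groups did not overlap for 27.2% of genes, against 10% expected by chance for 3 against 3. The fit with a variance trend and robust moderation, fixed before the data were examined as a second setting, called 522 genes, 401 higher and 121 lower, and normexp background correction called 115. Of the 522 genes, 112 were among those of normexp. The 522 did not hold on leaving out 1 array at a time. The trend and robust fit then called between 0 genes (without o-nitroanisole replicate 2) and 69 genes (without corn oil replicate 3), and 6 without corn oil replicate 1. Each such fit also has 1 array fewer, so lost power and dependence on single arrays cannot be told apart. Slide and scan divide the arrays exactly as the groups do, so the differences given here cannot be told apart from differences between slides.

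Cyp1a1 passed the threshold in the trend and robust fit (adjusted p = 0.0325 in that fit). The further genes named were taken from those past it there with a gene symbol (247 of the 522), LOC and RGD numbers left out. They were well above background on all 6 arrays, with groups that did not overlap, and were chosen after their values were seen. Among them the highest were Ccl20, a chemokine, at 2.73 ± 0.41 log2 (adjusted p = 0.0455 in that fit, 0.0961 with defaults), Cldn22 at 2.00 ± 0.28 (probes from 1.37 to 2.00), S100a8 at 1.76 ± 0.27, Alas2 at 1.55 ± 0.25 and the zinc transporter Slc39a4 at 1.44 ± 0.20. The lowest were the chloride channel Cftr at -2.34 ± 0.30 log2 (adjusted p = 0.0321 in that fit, 0.0837 with defaults), Ppp1r1b at -2.14 ± 0.33 (probes from -2.14 to -1.41), the amino acid transporter Slc7a12 at -1.86 ± 0.20, Fat3 at -1.71 ± 0.18 and Armh1 at -1.57 ± 0.24. SEs are those of the default fit. Under normexp the log2 difference was -1.30 for Cftr and -0.64 for Armh1, and Cldn22 was 2.15-fold higher. Each fold was over 1.5 times nearer to no change, the way in which the normexp offset moves dim probes.

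**Figure D1:**
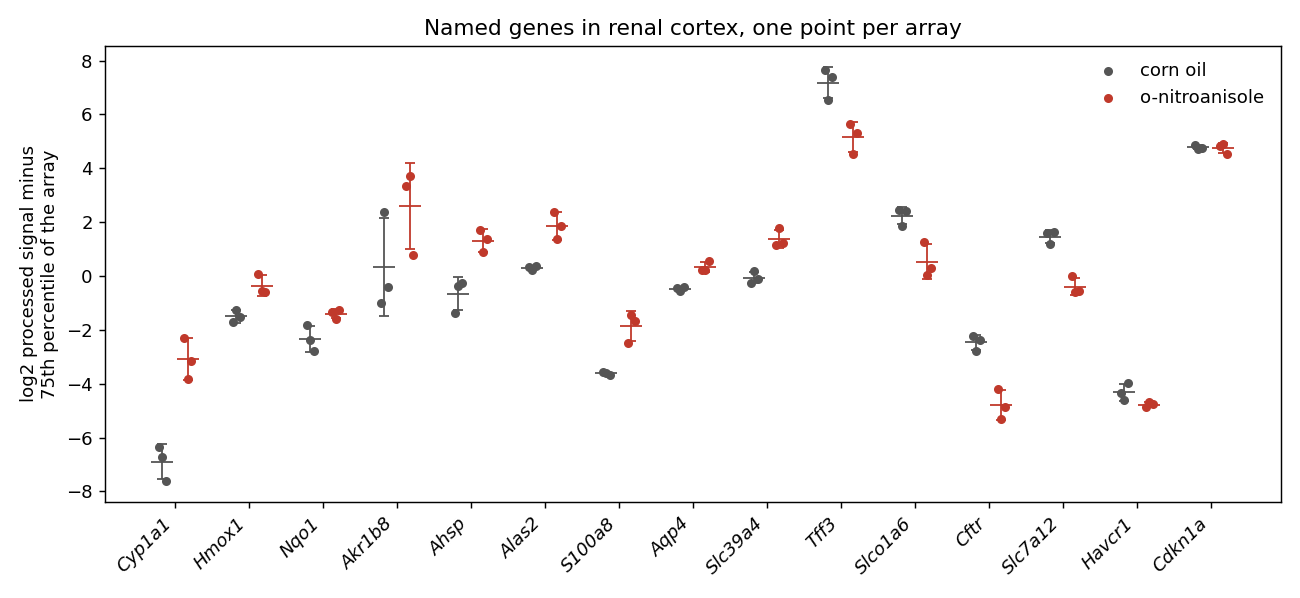
Log2 processed signal minus the array's 75th percentile for 15 named genes, with 1 point per array, a horizontal bar at the group mean and error bars of 1 SD over 3 arrays. Cyp1a1 in corn oil was below the level called well above background; Tff3 had a mean of 7.18 in corn oil and 5.16 in o-nitroanisole.

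Markers of red blood cells shifted higher as a list (camera, adjusted p = 7.2e-06), with a median log2 difference of 0.89 over 12 tested members, 11 of them higher. With an estimated correlation the adjusted p was 0.428. Adjusted over the list alone, 9 members were higher and 0 lower. Ahsp, the alpha globin chaperone, differed by 1.98 ± 0.36 log2, Alas2, which starts heme synthesis in erythroid cells, by 1.55 ± 0.25, and the beta globin Hbb by 0.67 ± 0.10, with probes at 0.67 and 1.26. S100a8 at 1.76 ± 0.27 and S100a9 at 1.15 ± 0.19, abundant in neutrophils, were also higher, while the neutrophil and mast cell list of 7 members gave adjusted p = 0.192 and the lymphocyte list, with a median of -0.06, gave 0.477.

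Markers of the collecting duct shifted higher (adjusted p = 1.1e-05, and adjusted p = 0.428 with an estimated correlation), with a median of 0.29 over 21 members, and adjusted over the list alone 10 were higher and 0 lower. Aqp4, a basolateral water channel, differed by 0.81 ± 0.11 log2, though its 4 probes ranged from 0.06 to 0.84. Slc4a9, an anion exchanger of intercalated cells, differed by 0.69 ± 0.10. Slc4a1 belongs to both this list and the red blood cell list; without it the adjusted p was 3.07e-05.

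NRF2 targets, genes of the antioxidant response, shifted higher (adjusted p = 0.0105, and adjusted p = 0.428 with an estimated correlation), beside the higher red blood cell markers, with a median of 0.26 over 24 members. Adjusted over the list alone, 11 were higher and 2 lower. Ephx1, an epoxide hydrolase, differed by 0.67 ± 0.06 log2, and the efflux pumps Abcc4 and Abcc2 by 0.94 ± 0.12 and 0.80 ± 0.11. Gclm and Gclc, the subunits of the enzyme that starts glutathione synthesis, were the 2 that were lower, at -1.24 ± 0.25 and -0.71 ± 0.23. The member with the largest difference, Akr1b8 at 2.28 ± 1.16, had an SD of 1.81 within corn oil and an adjusted p of 0.359, and ranged from 1.62 to 3.31 on leaving out 1 array. The call was lost without corn oil replicate 2 (adjusted p = 0.0776) and without o-nitroanisole replicate 1 (adjusted p = 0.0721). The AhR target list gave adjusted p = 0.247 over 6 members; beside Cyp1a1, the receptor's repressor Ahrr lay at -1.05 ± 0.19 log2.

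Immediate early genes shifted higher (adjusted p = 0.0015, and adjusted p = 0.428 with an estimated correlation), with a median of 0.21 over 20 members. Adjusted over the list alone, 3 were higher and 0 lower: Fos at 1.01 ± 0.17, Atf3 at 0.95 ± 0.15 and Ier3 at 0.36 ± 0.06 log2. Extracellular matrix genes shifted lower (adjusted p = 6.0e-05, and adjusted p = 0.428 with an estimated correlation), with a median of -0.21 over 26 members. Adjusted over the list alone, 7 were lower and 0 higher, among them the collagens Col1a2 at -0.50 ± 0.08 and Col3a1 at -0.51 ± 0.09 and the matrix protease Mmp2 at -0.99 ± 0.21. The growth factor Tgfb2, at -1.41 ± 0.61 with probes from -1.53 to -0.94, had an adjusted p of 0.292 and lay at -2.10 without corn oil replicate 1. The interferon response list shifted lower (adjusted p = 0.0098, and adjusted p = 0.746 with an estimated correlation), with a median of -0.34 over 28 members, of which 0 passed when adjusted over the list alone; Oas1k lay at -1.11 ± 0.57, and at -1.76 without o-nitroanisole replicate 3. That call was lost without corn oil replicate 1 (adjusted p = 0.0600) or 2 (0.0633) and without o-nitroanisole replicate 1 (0.124) or 2 (0.212). No list kept its call with an estimated correlation. That correlation was 0.592 for the interferon list and 0.332 for the red blood cell list. It was 0.217 for the collecting duct, 0.107 for extracellular matrix and 0.099 for immediate early genes. For NRF2 targets it was -0.003, under the preset 0.01, so a higher correlation does not account for that loss. With an estimated correlation, camera also refers its statistic to the 4 residual degrees of freedom. With a preset correlation, its degrees of freedom follow the number of genes. A call lost with an estimated correlation therefore need not reflect correlation between genes. Of 10 splits of the arrays into 3 and 3, 6, the real one included, called at least 6 lists by camera with the preset correlation. Fry asks whether a list moves one way on balance and, unlike camera, does not set it against the other genes. It called 11 of the 27 lists, and the interferon list was not among them. The counts of fry and camera therefore answer different questions.

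**Figure D2:**
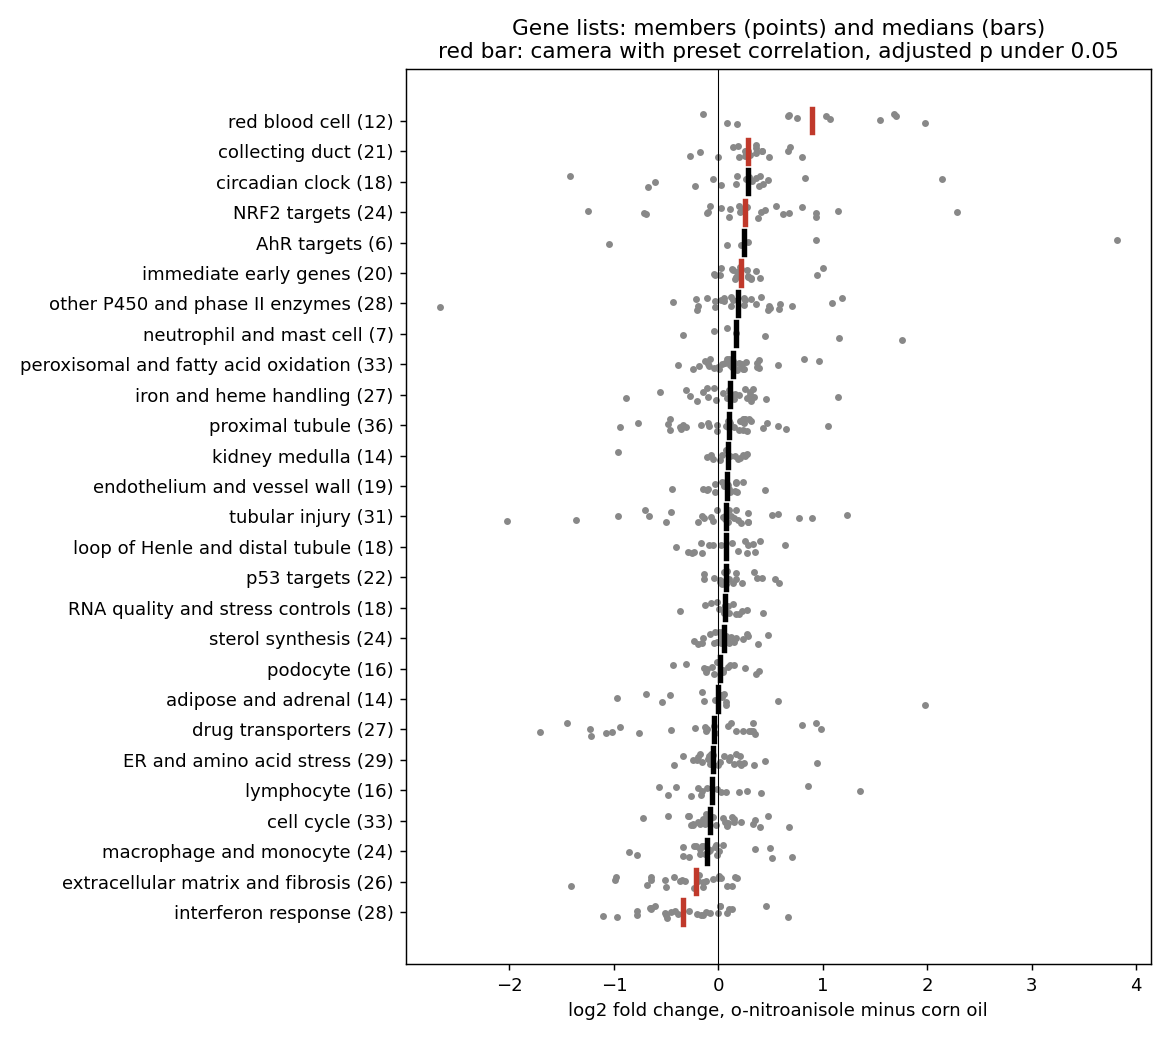
Log2 difference, o-nitroanisole minus corn oil, of each tested member (points) of 27 gene lists, with bars at list medians and the number of members in parentheses. Red bars mark the 6 lists with an adjusted p under 0.05 by camera with a preset correlation; the red blood cell list has the highest median, 0.89. The AhR point at 3.81 is the fitted value of Cyp1a1, which is not measured above background in corn oil.

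The other response lists did not pass camera at 0.05. Tubular injury genes gave adjusted p = 0.704 and went both ways: adjusted over the list alone, the keratins Krt18 at 1.23 ± 0.13 and Krt8 at 0.77 ± 0.10 log2 were among 4 higher, and Tff3 and Lcn2, the latter at -0.70 ± 0.14, were the 2 lower. Havcr1, the injury marker KIM-1, lay at -0.46 ± 0.17 (adjusted p = 0.227). Drug transporters gave adjusted p = 0.543, with 7 members higher and 7 lower when adjusted over the list alone; the organic anion transporters Slco1a6 and Slc22a7 lay at -1.71 ± 0.36 and -0.94 ± 0.13. The p53 target list gave 0.0936, with the exonuclease gene Aen at 0.55 ± 0.05, whose probes ranged from 0.01 to 0.55, and Gdf15 at 0.58 ± 0.25. Cdkn1a, the p21 inhibitor, lay at -0.04 ± 0.11, with probes from -0.49 to -0.04. The circadian clock list gave 0.0936: Ciart lay at 2.14 ± 0.55 (1.45 under normexp), Dbp at 0.83 ± 0.23 and Bmal1 at -1.42 ± 0.42. Adjusted p was 0.0859 for peroxisomal and fatty acid oxidation genes (Acaa1b at 0.96 ± 0.18), 0.192 for iron and heme handling and 0.410 for other P450 and phase II enzymes, where the male-predominant Cyp2c11 lay at -2.66 ± 1.51, at -4.37 without corn oil replicate 2 and at -1.60 without corn oil replicate 3. It was 0.631 for the cell cycle (Cenpf at -0.73 ± 0.38, with probes from -0.73 to 0.01), 0.677 for ER and amino acid stress and 0.622 for sterol synthesis.

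Among the other marker lists, adjusted p was 0.463 for the proximal tubule, where Glyatl2, on the list under the older name Keg1, lay at 1.05 ± 0.14 log2, and 0.893 for the loop of Henle and distal tubule, with Calb1 at 0.64 ± 0.33. It was 0.595 for the medulla (Cryab at -0.96 ± 0.39), 0.893 for podocytes (Pla2r1 at -0.44 ± 0.25) and 0.468 for endothelium and vessel wall. Macrophage and monocyte markers gave 0.225 with a median of -0.11, and adjusted over the list alone 3 were higher and 0 lower: Cd14 at 0.51 ± 0.08, Cd74 at 0.50 ± 0.11 and RT1-Da at 0.35 ± 0.08. Mrc1, at -0.85 ± 0.42 with probes from -1.64 to -0.85, did not pass. Cd79b, of the lymphocyte list, lay at 1.35 ± 0.81, at 0.48 under normexp and between 0.66 and 2.00 on leaving out 1 array, and was well above background on 1 of 3 corn oil arrays. Adipose and adrenal markers gave 0.468; Retn, whose brightest probe was not well above background on any corn oil array, had an adjusted p of 0.392. RNA quality and stress controls gave 0.221, with Hprt1 at 0.43 ± 0.06. Median, mean and camera direction differed in sign for lists near 0: tubular injury had a median of 0.08 and a mean of -0.04 with direction up, ER and amino acid stress a median of -0.05 and a mean of 0.03 with direction down, and lymphocyte a median of -0.06 and a mean of 0.05 with direction down. The loop of Henle list and the podocyte list had medians of 0.08 and 0.02 with direction down.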

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

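The alternatives for an adjusted p under 0.10, for symbol-bearing features alone, for the value table's numbering and for shared list genes, and the leave-one-out of the trend and robust fit, were chosen after seeing the data. The count of 0 genes held with quantile or median scaling, no dim filter, detection on all 6 arrays, outlier spots kept, probes averaged or tested singly, array weights, the value table and an adjusted p under 0.01. The normexp correction called 115 genes (76 higher, 39 lower, 15 at least 2-fold), the trend and robust fit 522 (401 higher, 121 lower, 54 at least 2-fold), symbol-bearing features alone 31 (19 higher, 12 lower, 7 at least 2-fold) and an adjusted p under 0.10 gave 359 (219 higher, 140 lower). Leaving out 1 array at a time gave 0 to 4 genes changed, 0 to 1 higher, 0 to 3 lower and 0 to 4 at least 2-fold, the 4 without corn oil replicate 3. The cause of these moves was not tested, apart from that of the trend. The replicate block called 0 genes and gave NRF2 targets an adjusted p of 0.0699, and it changed no other call; the replicate numbers are not shown to pair rats, since correlations of same-numbered arrays' deviations were 0.091, 0.058 and 0.026, under the 0.1 set for pairing, and o-nitroanisole replicate 3 went best with corn oil replicate 2 (0.034). With the value table's numbering the block also called 0 genes and changed no list call. The slide block was not run, since slide and group coincide. With an estimated correlation the adjusted p was 0.428 for NRF2 targets, extracellular matrix, immediate early genes, collecting duct and red blood cell, and 0.746 for the interferon response. Fry gave 0.684 for the interferon response and called p53 targets (0.0347), iron and heme handling (0.0383), circadian clock (0.0393), proximal tubule (0.0347), neutrophil and mast cell (0.0366) and RNA quality and stress controls (0.0393). Quantile scaling called the circadian clock (0.0316). Without a dim filter, p53 targets (0.0205), peroxisomal genes (0.0109) and the clock (0.0187) were called, and the trend and robust fit called peroxisomal genes (0.0478). Over the leave-one-out fits, adjusted p ranged from 0.0058 to 0.0776 for NRF2 targets, 1.2e-10 to 0.212 for the interferon response, 0.0312 to 0.999 for sterol synthesis, 0.0043 to 0.966 for lymphocyte, 0.0350 to 0.332 for p53 targets, 3.53e-04 to 0.527 for peroxisomal genes and 9.07e-04 to 0.765 for macrophage and monocyte. The red blood cell, collecting duct, extracellular matrix and immediate early lists passed in each leave-one-out fit, with highest values of 7.09e-04, 3.96e-04, 0.0034 and 0.0133. Cdkn1a, at -0.04 log2 (probes from -0.49 to -0.04), ranged from -0.108 to 0.0623 over those fits, above 0 without o-nitroanisole replicate 3 alone. For list and single-gene changes the cause was not tested. By construction, the normexp offset of 50 draws the folds of dim probes toward no change. Probes near background limit the dim genes, Cyp1a1 in corn oil among them.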

Other observations

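The tests of gene families, blood make-up and clock timing, and the count of splits for the default fit, were chosen after the result was seen; so were the random draws of genes set beside the brighter genes.

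Genes were grouped by the stem of their symbol, which gave 147 families of at least 10 tested members. By camera with the preset correlation 11 families passed an adjusted p of 0.05, 9 higher and 2 lower, and with an estimated correlation 0 did. Families of the mitochondrial respiratory chain and of proton pumps were among the higher ones, with an adjusted p of 0.818 each with an estimated correlation: Atp genes had a median log2 difference of 0.13 over 61 members (adjusted p = 4.61e-04), Cox genes 0.16 over 23 (0.0077), Ndufa genes 0.17 over 11 (0.0077) and Ndufb genes 0.18 over 10 (0.0115). Of the Atp genes, 4 also stand on the collecting duct list, which was higher by the same test with a median of 0.29 (adjusted p = 1.1e-05, and 0.428 with an estimated correlation): Atp6v0d2 at 0.49, Atp6v1g3 at 0.42, Atp6v1b1 at 0.20 and Atp6v1c2 at 0.14 log2. Mitochondrial ribosome genes, Mrpl, had a median of 0.12 over 42 (0.0022), and Mrps genes 0.11 over 24 (0.0264). With an estimated correlation the adjusted p was 0.818 for Mrpl and for Mrps genes. Under quantile scaling the medians of Atp, Cox, Ndufa, Ndufb, Mrpl and Mrps genes were 0.06, 0.05, 0.09, 0.05, 0.05 and 0.04. Klf genes, transcription factors, had a median of 0.28 over 13 (0.0077). Of the Klf genes, Klf1 at 0.75 log2 also stands on the red blood cell list. Klf4 at 0.14 and Klf6 at 0.15 also stand on the immediate early list. Slco genes, organic anion transporters, had a median of -0.54 over 11 (0.0388), and Col genes, the collagens among them, -0.23 over 17 (0.0121). With an estimated correlation the adjusted p was 0.866 for Slco genes and 0.818 for Klf and Col genes. The ribosomal Rps and Rpl genes were called higher (0.0115 and 0.0121, and 0.866 each with an estimated correlation), but their medians of 0.10 and 0.08 turned to -0.02 and -0.05 under quantile scaling.

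The fit with default moderation called 0 genes for the real groups, and the highest of the other splits of the 6 arrays into 3 and 3 was 1. All 10 splits give at least 0 by construction, so this comparison says nothing. At an unadjusted p under 0.05 the real groups gave 6142 genes and the others between 1007 and 1946. The trend and robust fit called 522 genes for the real groups, matched by 1 of 10 splits, the real one, and the highest of the others was 1. For gene lists by camera with the preset correlation, 6 of 10 splits, the real one included, gave as many as the 6 lists called, and the highest of the others was 10. With 10 splits a share under 0.05 is out of reach for any count. For the lists, 6 of 10 is also far above it, so the number of lists called does not set the real groups apart.

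Default moderation called 0 genes and the trend and robust fit 522. A candidate explanation is that the noise of dim probes lowers the degrees of freedom that limma shares between genes. The default fit on the brighter 16206 genes called 675 (517 higher, 158 lower), with 2.21 prior degrees of freedom against 1.76 over all genes and a median residual SD of 0.09 log2 against 0.20 in the dimmer genes, which gave 0 calls. In 20 random draws of 16206 genes the highest count was 3. The dimmer genes also had 2.26 prior degrees of freedom, so mixing genes of unlike noise may matter more than dimness alone, and the 675 remain subject to slide and scan.

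Erythroid genes were higher as a list by camera with the preset correlation, a call lost with an estimated correlation (adjusted p = 0.428). A labelling difference between slides that moves all probes alike could not be tested with the 7 E1A spike-in probes. Scaling each array by its own percentile removes such a shift before any comparison. With each spike-in probe centred over the arrays and the median taken per array, the groups differed by -0.015 ± 0.050 log2 (SE). The list median was 0.89, and no conclusion is drawn from the spike-in value. A slide effect on particular probes cannot be told apart from treatment. More blood of unchanged make-up in the treated tissue may account for the higher erythroid genes. The mean of 10 non-globin genes minus that of 2 globin genes differed between groups by 0.077 ± 0.126 log2 (SE). This is too wide to decide against a bound of 0.3. A changed make-up of the blood, with more young red cells, stays open by the same value.

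The circadian clock list did not pass camera (adjusted p = 0.0936), and adjusted over the list alone 1 member, Nr1d2 at 0.36 ± 0.07 log2, was higher and 0 lower. Differences were 0.83 for Dbp, 0.48 for Tef, -1.42 for Bmal1 and -0.67 for Npas2, none past the threshold. If they are real, a difference in the time of day of sampling may account for them. Within groups, the mean of 8 genes of the Dbp arm and the mean of 3 genes of the Bmal1 arm had Pearson r = -0.791 over 6 arrays (exact permutation p = 0.0278 one-sided, the smallest possible, and 0.0833 two-sided) and Spearman rho = -0.771 (exact p = 0.0278 two-sided). Without the 2 arrays farthest from the median r was -0.438, so the relation rests partly on those arrays. The group difference of the arms was 1.27 ± 0.44 log2 (SE, exact permutation p = 0.1 two-sided, the smallest that 3 against 3 allows), and sampling time, slide and treatment cannot be told apart.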
